A study of Mus musculus with 9 samples.

How the data were processed

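Total RNA from C2C12 myoblasts was labelled with biotin and hybridized to Affymetrix MOE430A arrays (3 puro, 3 pax7d) and MOE430B arrays (3 puro). The deposited values are intensity, as linear MAS5 signals per probe set; MAS5 is named in the submitters' processing notes, and its version and detection calls are not given. Each array had been scaled so that the mean over the middle 96% of probe sets was 1501 on MOE430A and 1500 on MOE430B. The array run records, of other units per the file headers, hold no expression value and were read only for the scan day, operator label, chip lot and fluidics station.

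The groups, gene lists, tests, rule for named genes and most alternatives were fixed before the data were examined. Probe sets were matched to gene symbols from the array annotation: on MOE430A 20380 named 1 gene, 691 several and 1555 none, and on MOE430B 14661, 245 and 7605. Genome coordinates were not used here. The values were used as deposited. On MOE430A, 64 control probe sets were left out, and a probe set was tested when at least 3 of the 6 arrays reached 463, the 40th percentile of all values; 8611 probe sets were below this filter. The fit was limma (version 3.58.1, R 4.3.3) lmFit and eBayes with an intensity trend on log2(value + 148), where 148 is the 20th percentile, pax7d minus puro, two-sided, with Benjamini-Hochberg adjustment. A gene was represented by its brightest tested probe set that names it alone. Means and SDs are of linear signals.

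Gene lists were counted over all probe sets and adjusted over the list alone, and those with at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over 30 lists; camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were alternatives. The genes named are 9 fixed genes (Pax7, Pax3, Myf5, Myod1, Myog, Myf6, Id1, Id2 and Id3), the 10 largest rises and 10 largest falls among called genes without overlap between groups whose higher group averaged at least 685, up to 4 called members per list with the smallest adjusted p or 1 member where none was called, and on MOE430B the 5 brightest genes found only there with up to 8 list members found only there. MOE430B values were described on log2(value + 220).

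Alternatives were quantile normalization, median centring, cyclic loess, other pseudocounts, no filter and a filter at the 60th percentile, no intensity trend, a robust variance model, array weights, a block on the sample number, a minimum log2 change of 1, the mean over a gene's probe sets, and leaving out each array. Camera used neither the intensity trend nor the robust variance model, so changing these could not alter its list calls. The operator label, chip lot and fluidics station as blocks and the scan day as a random block (statmod 1.5.0) were chosen after seeing the data; scan day as a fixed block could not be fitted with group.

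The fit was tested on simulated data where 200 of 14015 probe sets were changed. The simulated values had the means of these arrays and normal noise with the variances that the fit had estimated. They thus follow the fit's own variance model, and each result rests on 1 draw. The fit recovered 17.9% of 1.5-fold, 67.2% of 2-fold and 89.4% of 4-fold changes, called 6 unchanged probe sets, and called 0 when none was changed. Camera found the shifted list and 0 others. The simulated genes varied independently and every gene of that list was shifted alike, so this does not test lists whose genes vary together. Single values outside the fit were compared by a two-sided exact permutation test, for which 3 arrays against 3 allow no p under 0.1.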

Results

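The 9 arrays measured messenger RNA in C2C12 cells, a mouse myoblast line that divides in rich serum and can form muscle fibres when serum is withdrawn. The cells had been infected with a retrovirus and selected with puromycin. The control virus was empty (group puro), and the other virus was made to express a form of the paired-box transcription factor Pax7 that the labels call Pax7d (group pax7d). Both groups grew in DMEM with 10% fetal calf serum, without the serum withdrawal that leads to fibres. Whether any of the cells had differentiated was not tested. On the MOE430A design, which carries 22690 probe sets, there were 3 puro and 3 pax7d arrays. The MOE430B design, with 22575 probe sets of which 100 are also on MOE430A, was run on the same 3 puro samples only. The labels number the samples 1 to 3 in each group but do not say that they were separate cultures, so the p-values measure only the spread between these samples.

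The median signal per array was 704, 743 and 734 in puro 1 to 3 and 670, 670 and 588 in pax7d 1 to 3. On MOE430B it was 867, 880 and 873. The number of arrays limits the precision of every value. Across probe sets, Pearson's r between arrays was 0.946 to 0.956 within pax7d, 0.935 to 0.938 within puro and 0.888 to 0.941 between the groups; probe sets are not independent replicates. The ratio of the 3′ to the 5′ control probe set lay between 0.763 and 0.932 for Gapdh and between 0.987 and 1.18 for actin on the 9 arrays.

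The comparison of pax7d with puro asks which transcripts differ between the arrays labelled pax7d and puro. Pax7 itself did not read higher on the pax7d arrays, and the values do not show whether the viral transcript was made. The clearest rise was that of Plagl1, an imprinted zinc-finger transcription factor, at 9923 ± 596 (SD, n = 3) on the pax7d arrays against 29.4 ± 7.63 on the puro arrays, at least 21.4-fold higher by the only probe set of the gene that passed the filter. The other Plagl1 probe set read only 125 ± 31.2 against 29.3 ± 8.84, under the filter signal in both groups. The imprinted genes Peg3 (3.52-fold) and Mest were also higher, and Npnt, a matrix ligand of integrins, was 6.03-fold higher. Myf5, a myogenic regulatory factor, was 2.32-fold higher and Id3, an inhibitor of bHLH transcription factors, 2.44-fold higher. The Myf5 call held in 15 of 21 alternatives and the Id3 call in 20 of 21. Igfbp2, a secreted binding protein for insulin-like growth factors, was 6.55-fold lower, and the matrix genes Lox and Col6a3 were 2.93-fold and 2.34-fold lower. Genes of oxidative phosphorylation were higher as a group, and extracellular matrix, smooth muscle, inflammatory, homeobox, macrophage and endothelial genes were lower as groups by camera with a preset correlation. With an estimated correlation none of these 7 lists passed (adjusted p = 0.351, and 0.422 for the endothelial list).

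Of 14015 probe sets tested, 254 (186 genes) were higher and 162 (129 genes) lower on the arrays labelled pax7d at a limma adjusted p under 0.05, which is 2.97% of those tested. A log2 change of at least 1 was reached by 91 of the higher and 60 of the lower probe sets. The 3 values of one group lay entirely above or below those of the other in all 416 called probe sets and in 25.9% of all tested probe sets, where chance gives 10%. Of the called probe sets 61.1% were higher, but 82.2% were higher (461 against 100) when the arrays were centred on their medians, which moved the median log2 change of all tested probe sets by 0.15. The share was 48.5% (178 against 189) without pax7d 1 and 46.3% with the fluidics station as a block, so which direction was more frequent depended on the setting.

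No scan day held both groups, so scan day and group cannot be told apart. With the operator label as a block, 41 probe sets were higher and 17 lower; with the chip lot as a block, 109 and 62; with the fluidics station as a block, 19 and 22. These blocks leave 1 to 3 arrays per group for the comparison. Leaving out 1 array moved the counts to 132 and 64 without puro 2, 127 and 71 without puro 3, 97 and 89 without pax7d 2 and 93 and 82 without pax7d 3.

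**Figure D1:**
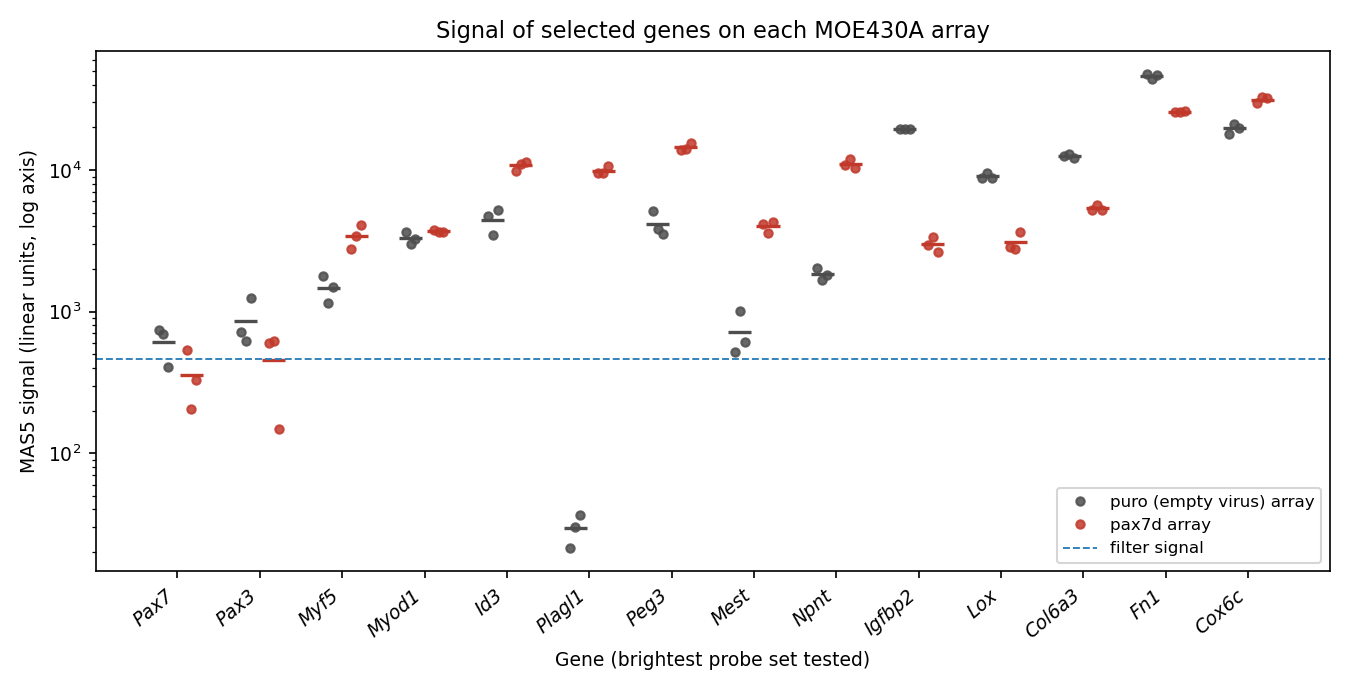
MAS5 signal (linear units on a log axis) of 14 genes on each MOE430A array, with puro arrays in grey and pax7d arrays in red; each dot is an array, each bar the mean of 3, and the dashed line the filter signal of 463. Plagl1, Peg3, Mest, Npnt, Id3, Myf5 and Cox6c lay higher on the pax7d arrays, Igfbp2, Lox, Col6a3 and Fn1 lay lower, and the groups overlapped for Pax7 and Pax3.

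Pax7 itself was not higher on the arrays labelled pax7d. Its only MOE430A probe set read 357 ± 168 on the pax7d arrays and 611 ± 181 on the puro arrays (SD, n = 3 each), a log2 change of -0.61 ± 0.37 (SE) with a limma adjusted p of 0.371. These signals were within the range of olfactory, vomeronasal and taste receptor probe sets, whose median was 250 and whose 95th percentile was 779. The values do not show whether the viral transcript was made, because the probe set need not match the viral sequence. For this reason the directions given here are those between arrays labelled pax7d and puro. Pax3, the paralog of Pax7, read 456 ± 266 against 861 ± 336 (adjusted p = 0.274).

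Among the myogenic regulatory factors, Myf5 rose from 1474 ± 321 to 3414 ± 649 (log2 change 1.14 ± 0.19 SE, adjusted p = 0.0104), but the call was lost without pax7d 2, without pax7d 3, without the intensity trend, and with each of the operator, chip lot and station blocks. Myod1 read 3703 ± 66.4 against 3291 ± 327 (adjusted p = 0.499). Myog and Myf6, which act later in differentiation, were below the filter with means of 323 and 98.2 on pax7d arrays and 374 and 108 on puro arrays. Of the Id genes, Id3 rose from 4469 ± 906 to 10770 ± 828 (adjusted p = 0.00143), a call lost with the station block. Id2 read 3574 ± 777 against 1701 ± 784 (adjusted p = 0.0592) and Id1 8976 ± 1995 against 8462 ± 739 (adjusted p = 0.853); the sign of the Id1 difference turned under quantile and cyclic loess normalization.

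The 10 largest rises were those of Plagl1, Lix1, Parm1, Blvrb, Npnt, Mest, Gpnmb, Trim54, Fam107b and Msln. Where all 3 arrays of a group were under the filter signal, the fold is a lower bound taken against that signal of 463. Taken against the receptor probe sets' 95th percentile of 779, each such bound would be smaller. Lix1 rose at least 5.41-fold (adjusted p = 7.38e-05), Trim54, a muscle RING-finger protein, at least 2.97-fold, Blvrb, a biliverdin reductase, at least 2.76-fold and Gpnmb, a transmembrane glycoprotein, at least 2.47-fold. Parm1 rose from 549 ± 323, a level near background, to 4647 ± 865 (adjusted p = 7.93e-04), Fam107b 4.74-fold and Msln (mesothelin) 4.67-fold. For Npnt, 2 of the 4 tested probe sets were called higher and the others were not called. The calls of Blvrb and Gpnmb were lost with the operator and station blocks, that of Parm1 with the operator block and that of Trim54 with the station block.

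The 10 largest falls were those of Igfbp2, Cldn3, Sema4g, Lalba, Sema6a, Oas2, Tnnt2, Tubb3, Nfatc2 and Fbln2. Igfbp2 fell from 19500 ± 102 to 2992 ± 372 (adjusted p = 8.62e-07). Cldn3, a tight junction protein, fell from 2478 ± 843 to 315 ± 184, a level near background, by 1 probe set (adjusted p = 0.0025), while its other probe sets were below the filter. The semaphorins Sema4g and Sema6a fell at least 2.21-fold and 1.88-fold, Lalba at least 2.38-fold and the interferon-induced Oas2 at least 2.32-fold. Tnnt2, a cardiac troponin T also made in embryonic muscle, fell 3.52-fold and the matrix protein Fbln2 3.02-fold. Tubb3 fell from 1960 ± 68.1 to 567 ± 80.7 and Nfatc2 from 1666 ± 330 to 512 ± 254, levels near background. All of these but Igfbp2 and Fbln2 lost the call with the station block, and all of these but Igfbp2, Fbln2 and Cldn3 lost it with the operator block; Sema6a and Nfatc2 lost it with the chip lot block as well.

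Of 57 named genes that were called, 16 were called in each of the 21 alternatives run on genes: Igfbp2, Lox, Gas1, Col6a3, Col18a1, Fhl1, Mest, Plagl1, Lix1, Npnt, Csrp2, Fam107b, Msln, Fbln2, Fn1 and Peg3. With the operator block 20 of the 57 kept the call, and with the station block 20. The other called genes lost the call in 1 or more alternatives. Scan day as a random block, 1 of the 21, kept all 416 calls at a negative correlation of -0.175. It is therefore no check on scan day. Besides the genes where it is said, Cdh2, Cebpb, Fn1, Gas1, Hmgcs1, Hoxa9, Igfbp5, Nfatc2, Ptgs2, Sdc2, Stmn2 and Vegfa had at least 1 further tested probe set that was not called, of the same sign. Without puro 2 the calls of Sema4g, Lalba, Sema6a, Nfatc2, Itga7, Cdk1, Sdc2, Ccl2, Ccl7, Ptgs2, Cebpb, Ebp, Cox8a, Sdhd, Ndufb5, Rpl11, Stmn2 and Laptm5 were lost, and without puro 3 those of the same genes except Itga7, Cdk1 and Ebp. Besides Myf5, those of Itga7, Sdc2, Ptgs2, Cebpb, Ebp, Sdhd, Ndufb5, Rpl11, Stmn2 and Laptm5 were lost without pax7d 2 and also without pax7d 3, those of Cdk1, Ccl7 and Cox8a without pax7d 2 and that of Sema6a without pax7d 3. Without pax7d 1 the calls of Sdc2, Ccl7, Ebp and Rpl11 were lost, and without puro 1 those of Sema6a, Itga7, Sdc2, Ptgs2 and Laptm5.

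Of 31 gene lists fixed beforehand, 30 had enough measured genes to test, and 7 passed camera at an adjusted p under 0.05, 1 up and 6 down. With an estimated correlation none of the 30 passed. Fry called 11 lists: those called by camera except the endothelial one, and also the imprinted and cholesterol lists (up) and the contractile, FGF, HGF and IGF, and serum lists (down). Of 686 list genes tested, 26 were higher and 29 lower.

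Oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase, were higher as a group. Of 51 tested, 6 rose and none fell over all probe sets, and 19 rose and none fell adjusted over the list alone. The 6 became 2 without puro 2, 1 without puro 3, 1 without pax7d 2 and 2 without pax7d 3, and 0 without the intensity trend or with the operator or station block. The median log2 change was 0.27 (camera adjusted p = 3.99e-08; adjusted p = 0.351 with an estimated correlation). Cox6c rose from 19670 ± 1652 to 31490 ± 1613 (adjusted p = 0.00419), and Cox8a, Sdhd and Ndufb5 rose 1.43-fold, 1.64-fold and 1.76-fold. Each has another tested probe set that was not called, with log2 changes of 0.07 for Cox6c, 0.03 for Sdhd, 0.63 for Ndufb5 and -0.40 for a dim one of Cox8a.

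Extracellular matrix genes were lower as a group. Of 48 tested, 2 rose and 9 fell, and 4 rose and 18 fell adjusted over the list alone. The 9 falls became 6 without puro 2, 5 without puro 3, 4 without pax7d 2 and 4 with the operator or station block. The median log2 change was -0.28 (camera adjusted p = 0.0187; adjusted p = 0.351 with an estimated correlation), and the call was lost with the operator block (adjusted p = 0.0571). Lox, a collagen cross-linking enzyme, fell from 9019 ± 431 to 3096 ± 475 (adjusted p = 2.22e-04). Col6a3 fell from 12610 ± 476 to 5382 ± 275, and fibronectin (Fn1) from 46020 ± 1831 to 25770 ± 309. Col18a1, a basement membrane collagen, went the other way, from 3232 ± 372 to 8553 ± 884 (adjusted p = 4.35e-04).

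Smooth muscle and actin cytoskeleton genes were also lower. Of 28 tested, none rose and 3 fell, and 8 fell adjusted over the list alone, with a median log2 change of -0.23 (camera adjusted p = 0.0187; adjusted p = 0.351 with an estimated correlation). The 3 falls became 6 without puro 1, 5 without pax7d 1, 5 under quantile and 7 under cyclic loess normalization. Csrp2 fell 2.40-fold, Fhl1 2.07-fold and Ccn2, a matricellular protein induced by TGF-beta, 2.94-fold. The camera call was lost without the filter (adjusted p = 0.0588), with the operator block (0.104), without puro 1 (0.0729) and without pax7d 1 (0.122).

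Inflammatory and chemokine genes were lower as a group, with 3 of 20 falling and none rising, 5 falling adjusted over the list alone, and a median log2 change of -0.50 (camera adjusted p = 0.00307; adjusted p = 0.351 with an estimated correlation). The 3 falls became 0 without puro 2 or puro 3, 1 without pax7d 2, 1 with the station block, and 0 without the intensity trend or with the operator or chip lot block. With dim genes at their bound the median was -0.24. The chemokine Ccl2 fell 2.08-fold and Ptgs2, a prostaglandin synthase, 1.52-fold. The chemokine Ccl7 fell from 1707 ± 166 to 780 ± 167, a level near background. The list missed the threshold without the filter (adjusted p = 0.0608).

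HOX and other homeobox genes, which pattern the body axis, were lower as a group: of 22 tested, none rose and 1 fell, 5 fell adjusted over the list alone, and the median log2 change was -0.41 (camera adjusted p = 0.00307; adjusted p = 0.351 with an estimated correlation). Hoxa9 fell from 3654 ± 244 to 1606 ± 279 (adjusted p = 0.00386). This call was lost with the operator and station blocks. Without the filter the adjusted p of the list was 0.0773.

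Markers of other cell types also differed. Macrophage and leukocyte markers were lower, with 2 of 9 falling, none rising, 5 falling adjusted over the list alone and a median log2 change of -0.76 (camera adjusted p = 0.00307; adjusted p = 0.351 with an estimated correlation). The 2 falls became 1 without any single array except pax7d 1, and 0 with the operator or station block. The receptor Csf1r fell from 2716 ± 217 to 1298 ± 126 by 1 of its 3 tested probe sets, the others not being called (adjusted p = 0.141 and 0.279), and Laptm5 fell 2.18-fold by its only probe set past the filter. Endothelial markers had a median of -0.51 (camera adjusted p = 0.0251; adjusted p = 0.422 with an estimated correlation), with none of 9 past the test over all probe sets or adjusted over the list alone. The tested endothelial genes had a median signal of 631, under the 95th percentile of 779 given above for sensory receptor probe sets. The median signal of the macrophage list was 826. Kdr read 883 ± 206 against 1363 ± 245 (adjusted p = 0.175). The endothelial call was lost in 11 of 23 alternatives, quantile normalization (adjusted p = 0.0579) and cyclic loess (0.0625) among them, as well as without puro 3 (0.116), pax7d 1 (0.0639) or pax7d 3 (0.0623). Of the 23, the runs without the intensity trend and with the robust variance model could not change it. The 4 measured epithelial markers were too few to test; of these Cldn3 fell, also adjusted over the list alone.

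**Figure D2:**
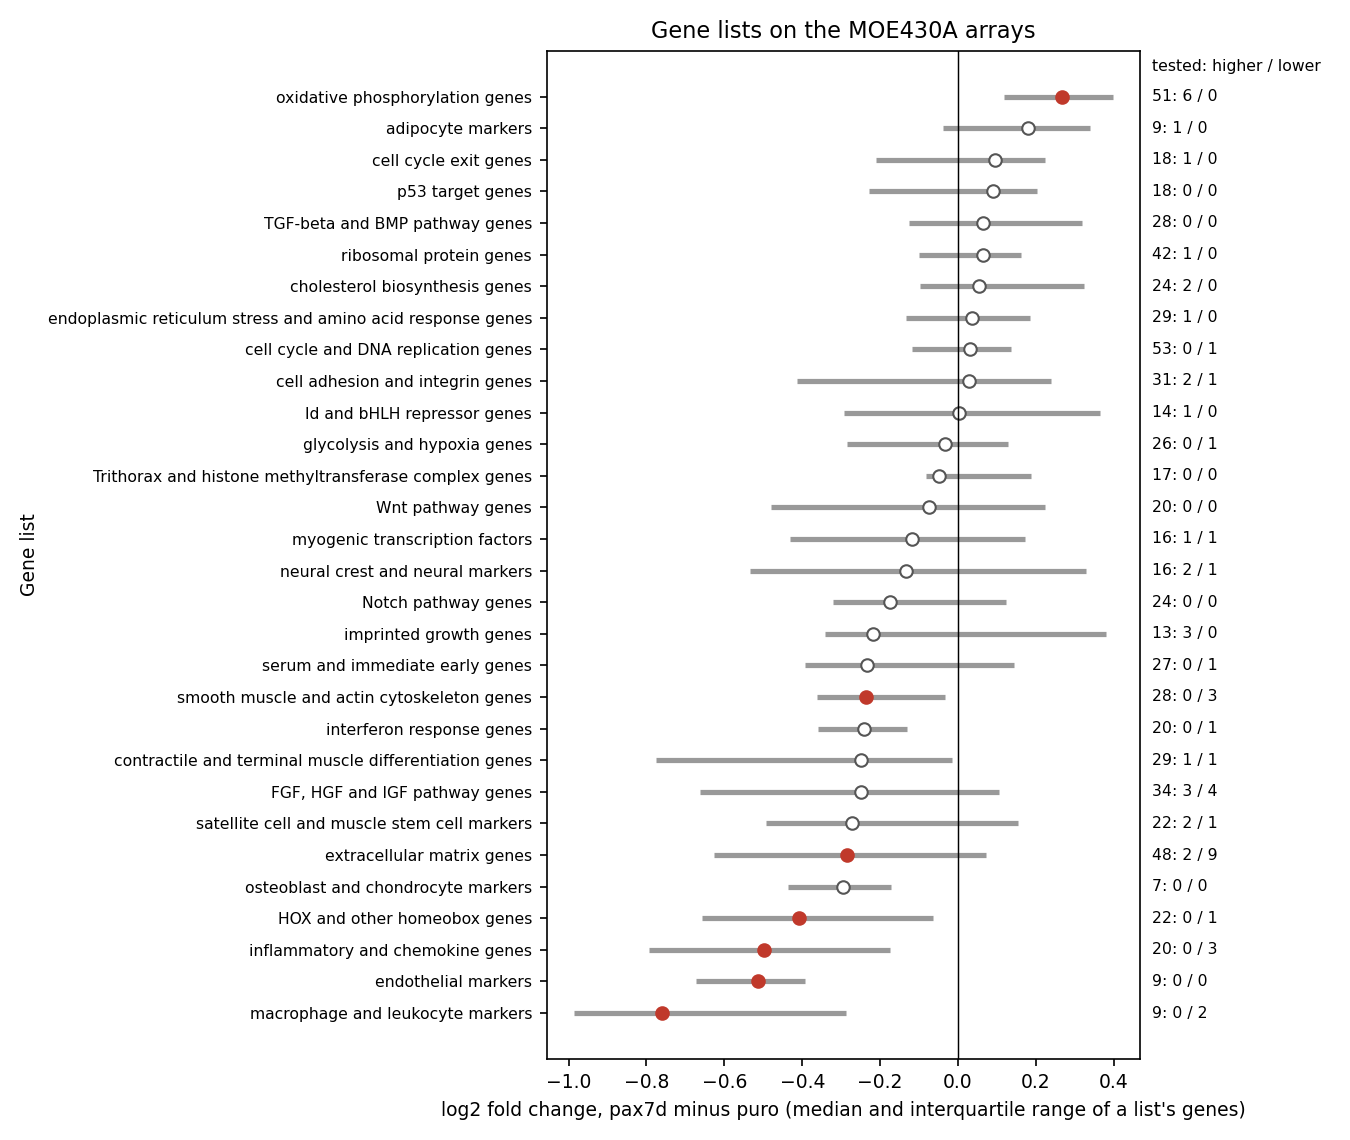
Median (circle) and interquartile range (bar) of the log2 fold change, pax7d minus puro, of the tested genes of each of 30 lists, with filled red circles for camera adjusted p under 0.05 at the preset correlation (none passed with an estimated correlation) and the genes tested, higher and lower at the right. Oxidative phosphorylation genes lay highest at 0.27 and macrophage and leukocyte markers lowest at -0.76.

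The muscle lists did not pass the test. Of 22 satellite cell and muscle stem cell markers, 2 rose (Myf5 and Cdh2, an adhesion cadherin, 1.76-fold) and 1 fell (Itga7, a laminin-binding integrin, 1.6-fold), with 3 and 3 adjusted over the list alone (camera adjusted p = 0.488); 18 of the 22 stand on another list too. Of 16 myogenic transcription factors, Myf5 rose and Ankrd1 fell 1.92-fold, with 1 and 2 adjusted over the list alone (camera adjusted p = 0.988). Of 29 contractile and terminal differentiation genes, Chrna1, an acetylcholine receptor subunit, rose 1.68-fold and Tnnt2 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.117). Of 53 cell cycle and DNA replication genes, none rose and 1 fell, Cdk1, a mitotic kinase, 1.46-fold, with 2 falling adjusted over the list alone (camera adjusted p = 0.667). Of 18 cell cycle exit genes, 1 rose, Gas1, a growth arrest protein, 2.83-fold, with 2 rising adjusted over the list alone (camera adjusted p = 0.198).

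Of 13 imprinted growth genes, 3 rose (Plagl1, Peg3 and Mest) and none fell, with 4 rising and 1 falling adjusted over the list alone. The list median was -0.22, its mean was 0.57 and camera pointed up (adjusted p = 0.117); the list passed fry (adjusted p = 0.00183, up), which does not compare it with other genes. Peg3 rose from 4155 ± 826 to 14480 ± 940 (adjusted p = 9.38e-05), and all 3 of its probe sets were called higher. Mest rose from 713 ± 258, a level near background, to 4007 ± 355 (limma adjusted p = 2.33e-04).

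Among the signalling lists, FGF, HGF and IGF pathway genes had 3 rises and 4 falls of 34, and 3 and 8 adjusted over the list alone (camera adjusted p = 0.117). Igfbp5 and Irs1, which act in insulin-like growth factor signalling, rose 2.09-fold and 1.90-fold, and Hbegf, an EGF family growth factor, fell 2.61-fold. Of 14 Id and bHLH repressor genes, Id3 rose, with 2 rising adjusted over the list alone (camera adjusted p = 0.190). None of 24 Notch pathway genes passed the test over all probe sets and 1 rose adjusted over the list alone (camera adjusted p = 0.867), with Adam10 reading 2989 ± 410 against 1800 ± 268 (adjusted p = 0.0517). None of 20 Wnt pathway genes passed either test (camera adjusted p = 0.988); the median was -0.07 and camera pointed up. Sfrp1, a secreted Wnt inhibitor, read 1707 ± 1012 against 3532 ± 1088 (adjusted p = 0.106). None of 28 TGF-beta and BMP pathway genes passed over all probe sets, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.160), with Tgfbr1 reading 1844 ± 95 against 1105 ± 122 (adjusted p = 0.0559).

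Of 31 cell adhesion and integrin genes, Cdh2 and Sdc2 rose and Itga7 fell, with 2 and 4 adjusted over the list alone (camera adjusted p = 0.750); the median was 0.03 and the mean -0.05. Of 20 interferon response genes, Oas2 fell, as it did adjusted over the list alone (camera adjusted p = 0.104). Of 29 endoplasmic reticulum stress and amino acid response genes, Cebpb rose 1.69-fold, also adjusted over the list alone (camera adjusted p = 0.384). None of 18 p53 target genes passed either over all probe sets or adjusted over the list alone (camera adjusted p = 0.858); the median was 0.09 and the mean -0.02. Polk read 886 ± 304 against 1457 ± 351 (adjusted p = 0.176). Of 27 serum and immediate early genes, Ccn2 fell, with 3 falling adjusted over the list alone (camera adjusted p = 0.160). Of 26 glycolysis and hypoxia genes, Vegfa, an endothelial growth factor, fell 2.04-fold, also adjusted over the list alone (camera adjusted p = 0.751).

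Of 24 cholesterol biosynthesis genes, Hmgcs1 and Ebp rose 1.84-fold and 1.56-fold, with 5 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.117). Of 42 ribosomal protein genes, Rpl11 rose 1.41-fold, with 2 rising adjusted over the list alone (camera adjusted p = 0.117); its call was lost under quantile and cyclic loess normalization. None of 17 Trithorax and histone methyltransferase complex genes passed over all probe sets or adjusted over the list alone (camera adjusted p = 0.697), with a median of -0.05 while camera pointed up. Dpy30 read 6128 ± 402 against 4814 ± 648 (adjusted p = 0.172). Of 9 adipocyte markers, Cebpb rose, with 2 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.14). None of 7 osteoblast and chondrocyte markers passed over all probe sets and 1 fell adjusted over the list alone (camera adjusted p = 0.128), with Sp7 reading 2687 ± 924 against 4946 ± 513 (adjusted p = 0.0536). Of 16 neural crest and neural markers, the myelin protein Pmp22 and Stmn2 rose 1.77-fold and 1.51-fold and Tubb3 fell, with 2 and 2 adjusted over the list alone (camera adjusted p = 0.988).

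The MOE430B arrays held control cells only, so they give levels and no comparison of groups. Of the 5744 genes found only on that design, the highest signals, which do not rank transcripts because probe sets differ in response, were those of Krt42 at 42620 ± 1244 (SD, n = 3), Atic at 42570 ± 5477, Fat1 at 38040 ± 1889, Tns3 at 34650 ± 4205 and Zfas1 at 32010 ± 5598. Of 30 list genes found only there, Dusp4, a MAP kinase phosphatase, read 21000 ± 1508, Myh10, a non-muscle myosin, 12610 ± 1943, Rbbp5 8686 ± 429, Megf10 8611 ± 2151, Gins2 8260 ± 1101, Hoxc10 7100 ± 997, Kmt2b 6004 ± 391 and Vgll2 5552 ± 538. A Pax7 probe set on this design read 162 to 250 in the puro samples. The median SD of a probe set across the 3 arrays was 0.41 on the log2 scale, against 0.25 on the puro MOE430A arrays, and Pearson's r across probe sets above the 40th percentile was 0.725 to 0.756. The 100 probe sets shared by both designs read 1.87, 1.87 and 1.77 log2 units higher on MOE430B in puro 1 to 3, so levels are not comparable across the designs.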

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

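The quantile, cyclic loess and estimated-correlation settings and the splits for counts of probe sets were planned; the other tests in this part, the use of those settings to weigh brightness among them, were chosen only after the result was seen. The control probe sets stand outside the main measurement, and 2 classes read higher on all 3 pax7d arrays than on any control array, while 2 others, the hybridization controls (ratio 0.496) and beta-actin (0.793), read lower on all 3. The hybridization controls are bacterial and phage sequences and read 14740 to 20100 on pax7d arrays against 24570 to 46410 on control arrays. So a difference between the arrays that is not one in mouse transcripts went along with group, and its cause was not tested. The 18S rRNA controls read 29200 ± 7361 against 12890 ± 6783 (SD, n = 3 each), a ratio of 2.27 (two-sided exact permutation test, p = 0.1, the smallest possible). The Bacillus transcripts dap, lys, phe and thr read 6346 ± 531 against 5416 ± 284, a ratio of 1.17 (exact permutation p = 0.1, the smallest possible). Both classes were picked because their groups do not overlap, which always gives this p, so it adds no support.

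Pax7 was not higher on the arrays labelled pax7d. A single wrong label would place an array beyond the midpoint toward the other group on the genes called without it. On a scale from 0 (control mean) to 1 (pax7d mean) the lowest pax7d array stood at 0.734 and the highest control array at 0.284. So no array lay beyond the midpoint. The genes used could differ by scan day, which cannot be told apart from group. The positions therefore cannot decide whether a label was wrong. The highest Pax7 signal on the 6 arrays, 736.7, was under the 95th percentile of receptor probe sets (779), in line with a probe set that reads background in both groups. Whether the virus carries the stretch the probes match was not tested and stays open.

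Oxidative phosphorylation genes were higher and 5 other lists lower. A difference between arrays that depends on brightness was argued against as the whole cause only at the preset correlation. There 6 of these 6 lists kept the camera call under quantile and cyclic loess normalization. Their medians lay outside the central 95% of 10000 random lists matched on signal, but the 6 lists had been picked for their calls. The random lists were drawn gene by gene, so that range is too narrow for lists whose genes vary together. With an estimated correlation in camera none of the 6 passed (adjusted p = 0.351). Brightness can still account for part of some medians. The matched lists had medians of 0.065 for oxidative phosphorylation (list 0.267), -0.144 for homeobox (-0.407) and -0.143 for macrophage genes (-0.76). For matrix, smooth muscle and inflammatory genes they were -0.004, 0.034 and -0.058. The endothelial list lost the call under both normalizations, its median going from -0.51 to -0.39 and -0.38 with an SD of its members of 0.22. It lay at percentile 1.75 of matched lists, so for it a brightness difference cannot be told apart from a real fall. For the macrophage markers, white blood cells in the control cultures cannot be told apart from a change within myoblasts: the mean log2 change of Lyz2 and Cd68 was 0.033, at signals near background; an effect of Pax7d also stays open, untested.

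Plagl1, Peg3 and Mest were higher. Taken alone, the operator, chip lot or station as the whole cause is argued against. Within the batches holding both groups the log2 change kept at least 0.799 of its size (Mest, operator label). For the operator this rests on 1 puro array and for the station on 1 pax7d array. The same genes kept their calls with each of these blocks, so this is no separate support. No puro array shared both operator label and chip lot with a pax7d array, so these factors acting together were not tested. Cross-hybridization at a single probe set is argued against for Peg3 by 2 other tested probe sets that were higher without overlap, but stays open for Plagl1, with 0 other probe sets past the filter, and for Mest, which has 1 probe set. The second Plagl1 probe set was higher without overlap, but at means of 125 against 29.3 it stayed under the filter signal. With 0 scan days that hold both groups, scan day cannot be told apart from group. An effect of Pax7d, or a difference between the infected cultures, stays open as untested.

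The 6 arrays make 10 splits, too few for a share under 0.05. The real split gave 254 higher, 162 lower and 416 changed probe sets, 7 lists and 55 list members, and the highest of the other splits gave 0, 0, 0, 2 and 0; in each case 1 split, the real one, gave as many. At an unadjusted limma p under 0.05 the real split had 2912 probe sets and the others 255 to 1131.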

How the results depend on the processing

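All 416 called probe sets kept their direction in every setting that tested them; for left-out arrays and blocks this follows from groups that do not overlap. The Pax7 log2 change stayed negative and uncalled throughout, from -0.86 to -0.38 without single arrays. The cause of the changes below was not tested, except that blocks and left-out arrays leave fewer arrays to compare. Counts of higher and lower probe sets were 461 and 100 with median centring, 87 and 69 without the intensity trend (28 list members, 36 named genes), 133 and 94 with sample number as a block, and 91 and 60 at a log2 change of at least 1 (25 members). The sample numbers do not pair the groups: deviations of like-numbered arrays had r of -0.104, 0.088 and -0.055. Of the alternatives chosen after seeing the data, the operator block gave 41 and 17 (17 members, 4 lists, 20 named genes), the chip lot block 109 and 62 (33 members), the station block 19 and 22 (15 members, 20 named genes) and scan day as a random block 752 and 768 (141 members) at a negative correlation of -0.175. Without the filter 3 lists passed, with an estimated correlation 0, and with fry 11. Shared probe sets were 1.57 log2 units higher on MOE430B after median centring, against 1.83 as deposited. Leaving out 1 array gave 93 to 327 higher, 64 to 189 lower, 32 to 70 members, 5 to 9 lists and 39 to 53 named genes; counts fell to 132 and 64 without puro 2, 127 and 71 without puro 3, 97 and 89 without pax7d 2, and 93 and 82 without pax7d 3.

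In 10 lists and Id1 the direction of an uncalled result turned, 48 times, never past the threshold (lowest adjusted p 0.592); the cause was not tested. Adjusted p for cell cycle, Notch and adhesion genes was 0.677, 0.990 and 0.990 with quantile normalization and 0.758, 0.983 and 0.983 with cyclic loess, where the Id1 log2 change was -0.028 and -0.029. It was 0.809 for Wnt with median centring, 0.999 for myogenic factors with pseudocount 1, 0.888 for satellite and for neural markers without the filter, 0.975 for cell cycle at the 60th percentile, 0.980 for neural markers with array weights and 0.920 for myogenic factors with the sample block. With the operator block it was 0.945 for Notch, 0.642 for Wnt and 0.841 for p53; with the chip lot block 0.878 for myogenic factors and 0.749 for neural markers; with the station block 0.786 for Notch and 0.899 for Trithorax; with scan day 0.956 for Wnt. With the mean over probe sets it was 0.786 for myogenic factors, 0.949 for Wnt and for adhesion and 0.919 for glycolysis, and with fry 0.869 for cell cycle, 0.592 for Wnt and 0.952 for p53. Without single arrays the ranges were 0.798 to 0.982 for myogenic factors, 0.751 to 0.967 for Wnt, 0.758 to 0.982 for neural markers, 0.657 to 0.891 for p53, 0.503 to 0.964 for glycolysis, 0.328 to 0.977 for Trithorax, 0.316 to 0.997 for cell cycle, 0.692 to 0.964 for Notch, and -0.064 to 0.253 (log2) for Id1. Signals near the receptors' 95th percentile of 779 limit what can be said of dim genes such as Pax7.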

Other observations

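The following gene families were chosen after their values were seen. Of 7 tested genes of the aryl hydrocarbon receptor pathway, 4 rose and none fell on the arrays labelled pax7d. Ahr, the receptor, rose from 587 ± 131, a level near background, to 2889 ± 118 (SD, n = 3 each, limma adjusted p = 2.33e-04). Nqo1, a quinone reductase, rose 2.19-fold and Tiparp 1.58-fold. The repressor Ahrr passed the test (adjusted p = 0.0419) at 700 ± 9.86 against 88.4 ± 52.6, levels under the receptors' 95th percentile of 779 in both groups, so no fold is given. Its classical targets Cyp1a1 and Cyp1b1 were not called (adjusted p = 0.930 and 0.643), nor was its partner Arnt (adjusted p = 0.703).

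Both tested hyaluronan synthases fell, Has1 2.23-fold and Has2 2.09-fold (adjusted p = 0.00648 and 0.00427). Of 11 semaphorins, 1 rose and 3 fell. Sema3e rose from 697 ± 183, a level near background, to 2408 ± 615 (adjusted p = 0.00403), Sema7a fell 1.75-fold (adjusted p = 0.0205), and Sema4g and Sema6a fell as given in the report.

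Among other control probe sets, the ratio of pax7d to control arrays was 0.496 for BioB, BioC, BioD and Cre and 0.793 for beta-actin. Each was lower on all 3 pax7d arrays than on any control array (two-sided exact permutation test, p = 0.1). Groups that do not overlap always give this smallest possible p. The ratio was 0.89 for Gapdh and 1.36 for Bacillus trpn.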
